A study of Mus musculus with 6 samples.

How the data were processed

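Gene expression was measured in whole lungs of mouse embryos at embryonic day 14.5 on 6 single-colour Affymetrix whole-transcript arrays, 3 from control embryos and 3 from mutant embryos. Per the labels' protocols, total RNA was purified on a silica column kit, copied with an oligo(dT) primer that carried a T7 promoter, amplified by in vitro transcription and labelled with biotin. Control embryos carried Shh-Cre, a Cre recombinase expressed from the Shh locus and so active in lung endoderm, the tissue that forms the lung epithelium. Mutant embryos carried Shh-Cre together with floxed (loxP-flanked) alleles of the forkhead transcription factor genes Foxp1, Foxp2 and Foxp4. The genotype label of the mutants writes Foxp1 a second time where the series title has Foxp2, and the title was followed. Both groups were on a mixed background of the strains C57BL/6 and 129X1. The replicate numbers come from the sample titles, and the series describes the 3 samples of each group as embryos.

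The deposited values are on a log2 scale and were made by the authors with the robust multi-array average (RMA), per the submitters' processing notes, which name oligo, RMA and limma without versions. RMA subtracts background, normalizes the arrays against each other and summarises the probes of a feature into 1 value. Its settings are not given in the sources used here, and the scanner files were not used here. RMA draws dim features toward a common floor and compresses large differences, so a fold change of a dim gene is a low estimate. The median value per array over all features lay between 6.70 and 6.79. The values carry no spot counts or detection calls, so the number of arrays, 3 per group, sets the precision.

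The table held 35556 features, of which 23410 have a row in the platform annotation. A single gene symbol is given for 21797 of them and several symbols for 1613, and 12146 features are unnamed here. Of the single-symbol features, 21698 matched a mouse gene of the RefSeq annotation of assembly GRCm38.p6 by Entrez identifier, which changed 0 symbols. That assembly was used only for names and for which genes neighbour each other, since the series names no genome build, and no coordinates are given. Single-symbol features entered the test, and a gene with several features, as 999 genes had, was represented by the one with the highest mean over the 6 arrays, which left 19946 genes. No gene had features called in opposite directions. Of 64 changed genes with several features, 32 had at least 1 feature that did not pass the threshold.

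The log2 values were compared between mutant and control lungs with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, genotype as the only term, all 6 arrays), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Values are given as log2 differences, mutant minus control, with the standard error (SE) of the moderated fit, or as group means with the standard deviation (SD) of n = 3 arrays. The fit had 7.96 moderated degrees of freedom. Gene lists for lung cell types, other organs, tissues that a dissection can carry over, signalling pathways, cell cycle and stress, 37 in all with 801 entries, were written before the data were examined, as were the tests, the alternatives and the rule for the genes named. Of the 757 distinct genes in them, 712 were measured. A listed name that is not an official symbol was matched through its synonyms. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 37 lists, and again with the correlation estimated from the arrays and with fry, which tests whether the genes of a list move one way on balance.

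The genes named are Foxp1 to Foxp4, the 12 largest rises and 12 largest falls among genes past the threshold whose mutant values all lie on one side of the control values, and, per list, up to 4 members past the threshold with the largest difference. In a list with none, the 2 members with the smallest p are given as values only. Unnamed gene models, pseudogenes, microRNAs and small nucleolar RNAs were left out of the largest rises and falls. Any gene named outside this rule is marked as chosen after its values were seen.

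The alternatives were quantile normalization applied again, centring of each array on its median, leaving out the dimmest genes (the lowest 1 of 3 parts by mean), testing all features, averaging the features of a gene, a mean-variance trend with robust moderation, array weights (with statmod 1.5.0 installed), the replicate number as a block, embryo sex read from Xist and Y-linked genes as a covariate, each array left out in turn, thresholds of 0.1 or of 1.5-fold, and other set tests. The median of the heart muscle list as a covariate was added after seeing the data. The comparison was tested on simulated data for the 19946 genes with known changes in some of them. It recovered 50 of 67 genes changed 1.5-fold (74.6%), 65 of 67 changed 2-fold (97%) and 66 of 66 changed 4-fold (100%), and 7 of its 188 calls were false (3.72%). In the same simulation, which had independent noise between genes, camera found the 1 list shifted by 0.3 log2 units and called 0 of the 36 other lists. Figures were drawn with matplotlib.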

Results

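RNA of whole embryonic lungs was profiled at E14.5, when the mouse lung epithelium is branching, in 3 control embryos carrying Shh-Cre and 3 mutant embryos in which Shh-Cre acted on floxed alleles of Foxp1, Foxp2 and Foxp4. The study addressed the part these forkhead transcription factors play in the identity of the lung endoderm. Each array gave 35556 features, and 19946 genes were compared. Over all genes the lowest correlation between arrays was 0.998 within the controls and 0.994 within the mutants, and it lay between 0.988 and 0.991 across the groups. The median SD per gene was 0.061 log2 units in controls and 0.095 in mutants. Judged by Xist and Y-linked genes, control 3 and mutant 3 came from male embryos and the other 4 from female embryos.

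Of the 3 targeted genes, Foxp2 and Foxp4 were lower in mutant lungs and Foxp1 did not pass the threshold. Foxp2 (feature 10536444) read 10.52, 10.54 and 10.53 in controls 1 to 3 and 9.59, 9.55 and 9.60 in mutants 1 to 3, a log2 difference of -0.95 ± 0.05 (SE, n = 3 per group) or 1.93-fold, with a limma adjusted p of 4.75e-05. Foxp4 (feature 10451613) read 9.43, 9.37 and 9.40 in controls and 8.75, 8.56 and 8.96 in mutants, a difference of -0.64 ± 0.10 or 1.56-fold (adjusted p = 0.00591). Foxp1 (feature 10546661) read 9.68, 9.73 and 9.75 in controls and 9.45, 9.25 and 9.55 in mutants, a difference of -0.31 ± 0.08 (adjusted p = 0.0661). All 3 mutant values lay below all 3 control values for each of these genes. Without mutant 3 the Foxp1 difference was -0.37 and passed the threshold (adjusted p = 0.0428). Foxp3, the family member that marks regulatory T cells and was not targeted, read 6.27 ± 0.05 (SD) in controls and 6.22 ± 0.02 in mutants (adjusted p = 0.69). Where the features lie relative to the deleted exons was not analysed here, and whole lung contains mesenchyme that Shh-Cre does not reach, so these levels are a limited check of the genotype.

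**Figure D1:**
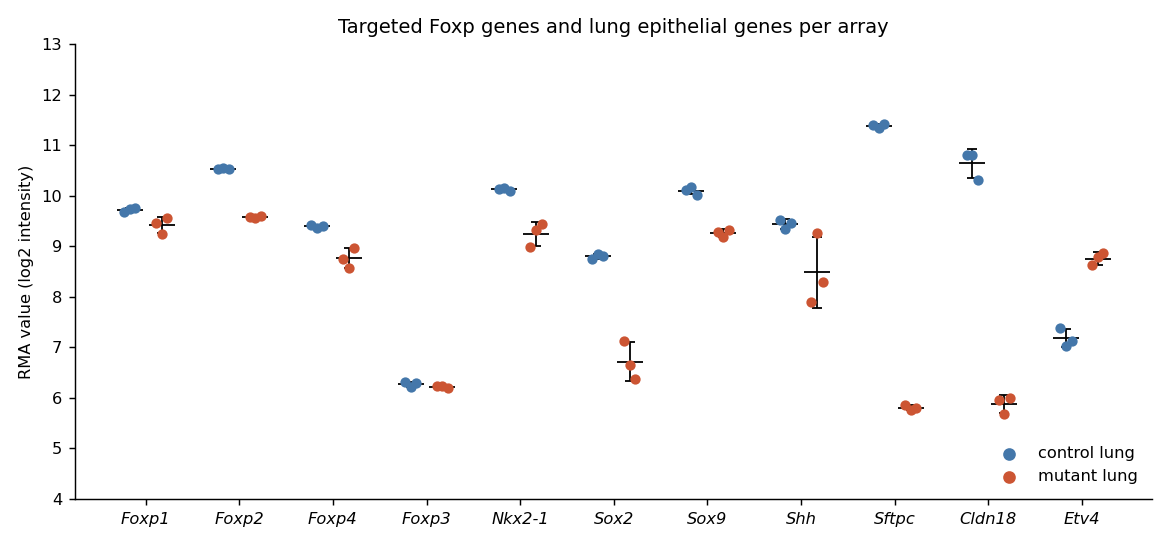
RMA values (log2 intensity) of the targeted genes, Foxp3 and selected lung epithelial genes in the 3 control and 3 mutant lungs, with 1 point per array and the group mean ± SD. Sftpc lies near 11.4 in all controls and near 5.8 in all mutants, while the mutant values of Shh run from 7.89 to 9.25.

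In the whole comparison, 1528 of the 19946 genes (7.66%) differed between mutant and control lungs, 765 of them higher and 763 lower in the mutants. At least 2-fold changes numbered 75 up and 116 down, and at least 4-fold changes 11 up and 21 down. The mutants lay wholly on one side of the controls for 25.9% of the genes tested, where chance gives 10%. An unadjusted p under 0.05 was reached by 3957 genes. The count of changed genes fell to 876, 793 and 774 without control 1, control 2 and control 3, and to 828 when all features were tested. With the fold also required to be at least 1.5 it was 549.

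The largest fall was that of Sftpc, the surfactant protein gene of distal lung epithelium, from 11.38 ± 0.03 (SD, n = 3) in controls to 5.80 ± 0.05 in mutants. This is a log2 difference of -5.58 ± 0.06 (SE) or at least 47.9-fold (adjusted p = 2.6e-09), since the mutant values lie near the level of genes silent in one sex (up to 5.77). Cldn18, a tight junction gene with a lung and a stomach form, was at least 27.2-fold lower (-4.77 ± 0.15, adjusted p = 3.14e-06). Aldh1a7, an aldehyde dehydrogenase, was 19.5-fold lower (-4.28 ± 0.18), and Cym, which encodes the protease chymosin, 16.7-fold lower (-4.06 ± 0.37), with a wide spread between controls (SD 0.87). Tinag (-3.95), the mucin Muc1 (-3.40) and the peptide transporter Slc15a2 (-3.37) were each more than 10-fold lower. The cholecystokinin receptor Cckar (-2.94), the complement factor Cfi (-2.78), Anxa1 (-2.76), the smooth muscle myosin Myh11 (-2.57) and Clu (-2.52) completed the 12 largest falls, with adjusted p from 1.08e-05 to 0.00263.

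The largest rise was that of Trf, which encodes the iron carrier transferrin, from 8.11 ± 0.22 (SD, n = 3) in controls to 11.62 ± 0.15 in mutants. It was 11.4-fold higher (3.51 ± 0.12 SE, adjusted p = 5.49e-06). Apela, a peptide ligand of the apelin receptor, was 8.01-fold higher (3.00 ± 0.24), and Fst, which encodes the activin antagonist follistatin, 7.17-fold higher (2.84 ± 0.23). The carbonic anhydrase Car4 was 5.78-fold higher (2.53 ± 0.50, adjusted p = 0.0201), with mutant values of 8.94, 9.35 and 7.08, and it no longer passed without control 1, control 2 or control 3 (adjusted p 0.0769, 0.0724 and 0.0855). Mab21l2 (2.46), Cpn1 (2.35), Emb (2.27), the tight junction gene Cldn8 (2.23), the secreted Wnt antagonist Frzb (2.23), the glycine decarboxylase Gldc (2.19), Asb4 (2.10) and Tspan12 (1.91) followed. The other 11 of these 12 genes had adjusted p from 5.49e-06 to 0.000688.

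**Figure D2:**
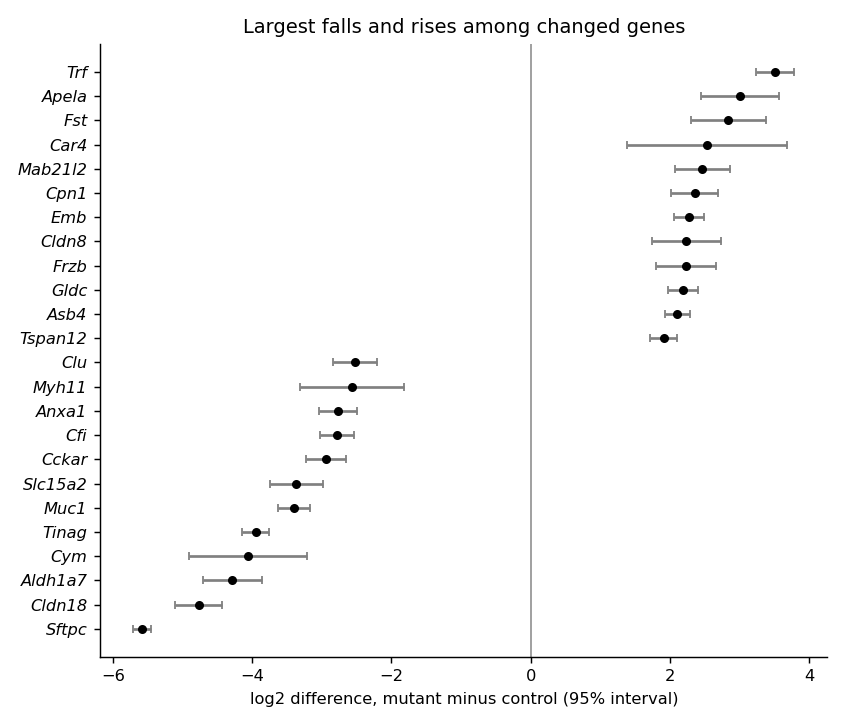
Log2 difference, mutant minus control, of the 12 largest falls and 12 largest rises among named genes past the threshold, as points with 95% confidence intervals from the limma fit of 3 against 3 arrays. The falls reach -5.58 (Sftpc) and the rises 3.51 (Trf), and the interval of Car4 is the widest.

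Genes of the lung epithelium were lower in the mutants. In the list for alveolar type I and type II cells, 15 of 24 measured members fell, 1 rose and 8 did not pass, with a median difference of -0.52 (camera adjusted p = 1.08e-17, and adjusted p = 0.0211 with an estimated correlation). Adjusted over the list alone, 18 fell and 1 rose. After Sftpc, Cldn18 and Muc1 its largest change was that of Egfl6 (-1.74 ± 0.21, adjusted p = 0.00201). The member that rose was the fatty acid desaturase Scd1 (0.60), named after its value was seen. In the list for distal tip progenitors, 8 of 17 members fell, 1 rose and 8 did not pass (median -0.48, camera adjusted p = 2.64e-07, adjusted p = 0.0633 with an estimated correlation). Adjusted over the list alone, 10 fell and 2 rose. The homeobox genes Irx2 (-1.50 ± 0.07) and Irx1 (-1.33 ± 0.07) were lower, with adjusted p of 1.98e-05 and 4.75e-05, while the ETS factor Etv4 was higher (1.58 ± 0.10, adjusted p = 0.000108). Nkx2-1, the homeobox gene that marks the lung and thyroid endoderm, was chosen after its value was seen and was lower, at 10.12 ± 0.04 (SD, n = 3) in controls and 9.25 ± 0.24 in mutants (adjusted p = 0.0026).

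Some proximal airway genes were lower as well. In the list for proximal airway and secretory cells, 7 of 20 members fell, 0 rose and 13 did not pass (median -0.15, camera adjusted p = 2.46e-06, adjusted p = 0.0726 with an estimated correlation), and 8 fell adjusted over the list alone. After Aldh1a7 these were led by Cldn10 (-2.40 ± 0.21), by Sox2, the transcription factor of the proximal airway (-2.08 ± 0.17, adjusted p = 0.000297), and by the club cell cytochrome Cyp2f2 (-1.35 ± 0.14). Genes shared by most epithelia also fell, in 17 of 29 members, with 0 rises and 12 that did not pass (median -0.44, camera adjusted p = 9.11e-15, adjusted p = 0.28 with an estimated correlation). Adjusted over the list alone, 21 fell and 1 rose. The keratins Krt7 (-1.44 ± 0.06) and Krt8 (-1.03 ± 0.13), the ETS factor Elf5 (-1.37 ± 0.13) and the epithelial splicing regulator Esrp2 (-1.15 ± 0.10) changed most.

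The other airway cell lists were not called by camera. Few of their members read above the array median in controls. These were 5 of 25 ciliated, 4 of 19 neuroendocrine, 1 of 18 goblet and 1 of 25 stratified genes. Dim genes cannot fall far here, so members that did not pass are not shown to be unchanged. Of 25 genes of multiciliated cells, 3 fell, also when adjusted over the list alone, and 22 did not pass (camera adjusted p = 0.0703). They were Tppp3 (-0.88 ± 0.06, adjusted p = 0.000182), Ccno (-0.38) and Myb (-0.37), and the calls of the last 2 ended with single arrays left out (adjusted p up to 0.128 without control 1 for Ccno and 0.0938 without control 2 for Myb). Of 19 neuroendocrine genes, 2 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.596). Ccn3 was at -0.91, Cplx2 at -0.28 and Cacna2d1 at 0.36, with adjusted p up to 0.0616 without control 3, 0.165 without control 2 and 0.159 without control 1. Of 18 goblet cell genes, Clca3a1 rose (0.73 ± 0.10) and Foxa3 fell (-0.45), the latter with an adjusted p of 0.0687 without control 3, and adjusted over the list alone 2 rose and 2 fell (camera adjusted p = 0.218). Of 25 genes of basal and stratified epithelium, 2 rose and 1 fell, and 3 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.629). The desmosomal cadherin Dsc3 was at 1.00, Evpl at -0.34 and the basal cell factor Trp63 at 0.34, with adjusted p up to 0.0555 without control 2, 0.154 without control 3 and 0.124 without control 3.

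**Figure D3:**
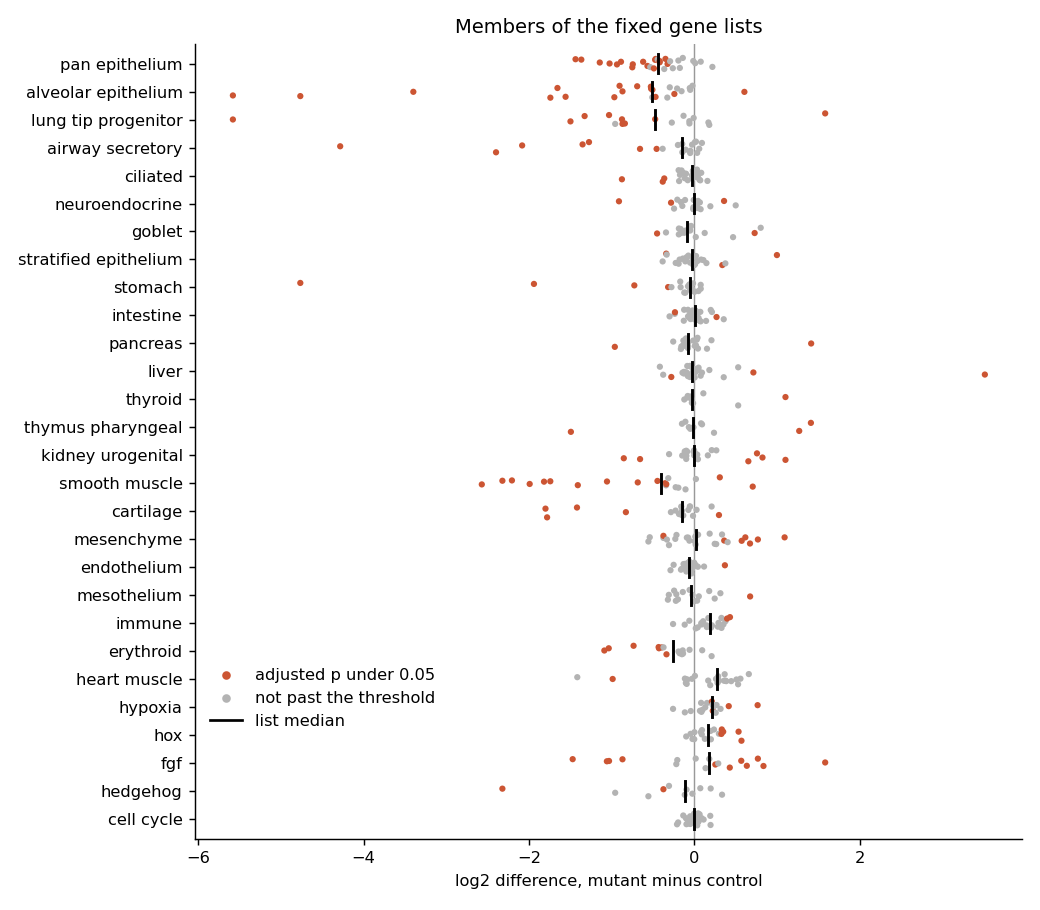
Log2 difference, mutant minus control, of the measured members of 28 of the 37 lists, with 1 point per gene, genes past an adjusted p of 0.05 in red, and a black bar at each list's median. The alveolar, tip, pan-epithelial and smooth muscle medians lie between -0.52 and -0.40, and cell cycle genes have no member past the threshold.

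Many smooth muscle genes, which belong to the mesenchyme and not to the epithelium in which Shh-Cre acts, were lower. In the list for airway and vascular smooth muscle, 12 of 20 members fell, 2 rose and 6 did not pass (median -0.40, camera adjusted p = 2.81e-11, adjusted p = 0.0633 with an estimated correlation). Adjusted over the list alone, 16 fell and 2 rose. Myh11 went from 10.18 ± 0.06 (SD, n = 3) to 7.61 ± 0.78, and the contractile genes Cnn1 (-2.21 ± 0.37, SE) and Actg2 (-1.99 ± 0.13) and the hedgehog-binding gene Hhip (-2.32 ± 0.17) fell too. Mutant 1 lay above mutants 2 and 3 in Myh11 (8.50 against 7.03 and 7.30) and Cnn1 (8.28 against 6.73 and 6.76) and below them in Hhip (7.39 against 8.20 and 7.78). The members that rose, named after their values were seen, were desmin (Des, 0.70), an intermediate filament gene of all muscle, and the integrin Itga8 (0.31), whose call ended without control 3 (adjusted p = 0.146). The median of this list relative to the control means was -0.47, -0.56 and -0.50 in mutants 1 to 3. The heart muscle list differed between the same arrays, at 1.10, -0.20 and -0.16.

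Cartilage genes of the airways fell in 4 of 18 members and rose in 1, with 13 that did not pass (median -0.15, camera adjusted p = 0.000474, adjusted p = 0.361 with an estimated correlation), and adjusted over the list alone 6 fell and 2 rose. The falls were Cytl1 (-1.80 ± 0.15), Mia (-1.78 ± 0.11), chondromodulin (Cnmd, -1.42 ± 0.15) and Matn4 (-0.83 ± 0.07). In the list for lung mesenchyme and fibroblasts, 6 of 27 members rose and 1 fell, with 20 that did not pass, and adjusted over the list alone 7 rose and 4 fell (camera adjusted p = 0.183). The paired-related homeobox gene Prrx1 (1.09 ± 0.07, adjusted p = 9.29e-05), the growth factor gene Fgf10 (0.77 ± 0.06) and the Wnt effector Lef1 (0.61 ± 0.08) rose. Lum (0.67) passed as well, with an adjusted p of 0.133 without control 2. Of 16 mesothelial genes, Lrrn4 rose (0.67, adjusted p = 0.0725 without control 1), 0 fell, and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.656).

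Members of the signalling lists moved in both directions, and none of these lists was called by camera. Of 17 genes of FGF signalling, 7 rose and 4 fell, and 9 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.218). The receptors Fgfr4 (-1.47 ± 0.10), Fgfr3 (-1.06 ± 0.06) and Fgfr2 (-1.03 ± 0.07) fell, with adjusted p of 0.000119, 7.27e-05 and 0.000122, while Etv4 rose. The related gene Etv5, named after its value was seen, went the other way (-0.87 ± 0.11, adjusted p = 0.00294). Of 11 hedgehog pathway genes, Hhip and the mesenchymal forkhead gene Foxf1 (-0.38, adjusted p = 0.0989 without control 1) fell and 0 rose, and adjusted over the list alone 4 fell and 2 rose (camera adjusted p = 0.106). Shh itself and its receptor gene Ptch1, chosen after their values were seen, were at -0.96 ± 0.29 and -0.56 ± 0.17 and did not pass (adjusted p 0.101 and 0.108). Without mutant 2, whose Shh value was 9.25, both passed, at -1.34 (adjusted p = 0.00104) and -0.75 (adjusted p = 0.0138). That value was the highest among the mutants, so leaving it out favours a fall and these p values are no support for one. Of 17 Wnt feedback targets, 5 rose and 2 fell, and 6 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.596). The Wnt deacylase Notum (0.97 ± 0.09), Lef1 and Myc (0.46, adjusted p = 0.0818 without control 2) rose, and Sox9, also a marker of the distal tips, fell (-0.84 ± 0.07).

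Of 15 BMP pathway genes, 1 rose and 2 fell, and 2 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.634). Bmp5 was at -0.44, the antagonist Nog at -0.36 and the antagonist Grem1 at 0.37, with adjusted p up to 0.171 without control 3, 0.139 without control 3 and 0.0673 without control 2. Of 17 Notch pathway genes, 2 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.596). Lfng (-0.63 ± 0.10) and Hey2 (0.46 ± 0.07) changed under every array left out, while Notch1 (-0.45) and Notch2 (0.32) had adjusted p up to 0.0665 without control 2 and 0.123 without control 1. Of 13 genes of retinoic acid synthesis and response, 3 rose and 2 fell, and 4 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.992). The retinoic acid binding protein gene Crabp2 rose (1.39 ± 0.20) and the synthesis enzyme Aldh1a1 fell (-1.35 ± 0.21), while the retinol carrier receptor Stra6 (0.76) and the receptor Rarb (-0.53) had adjusted p up to 0.125 without control 2 and 0.0852 without control 1.

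Of the lists for other endodermal organs, only that for stomach epithelium was called. In it, 4 of 23 members fell, 0 rose and 19 did not pass, with a median of -0.06 (camera adjusted p = 0.00123, adjusted p = 0.436 with an estimated correlation), and 5 fell adjusted over the list alone. Besides Cldn18 these were the cathepsin Ctse (-1.94 ± 0.15), the pepsinogen gene Pgc (-0.73 ± 0.09) and Gkn3 (-0.32, adjusted p = 0.13 without control 3). Of 30 intestinal genes, Mttp (0.27) rose and Slc5a1 (-0.24) fell, also when adjusted over the list alone (camera adjusted p = 0.998), with adjusted p up to 0.177 without control 3 and 0.146 without control 2. Of 24 pancreatic genes, the LIM homeobox gene Isl1 rose (1.41 ± 0.19) and the acinar factor Rbpjl fell (-0.96 ± 0.09), also when adjusted over the list alone (camera adjusted p = 0.171). Of 26 liver genes, 2 rose and 1 fell, and 3 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.98). Besides Trf these were the fibrinogen gene Fgg (0.71 ± 0.11) and Afp (-0.28, adjusted p = 0.127 without control 3). Of 11 thyroid genes, 1 rose, the paired box gene Pax8 (1.10 ± 0.10, adjusted p = 0.000413), also when adjusted over the list alone (camera adjusted p = 0.847). Few members of these organ lists read above the array median in controls. These were 2 of 23 stomach, 0 of 30 intestinal, 1 of 24 pancreatic, 3 of 26 liver and 1 of 11 thyroid genes. Members that did not pass are thus not shown to be unchanged. Cldn18, the largest fall of the stomach list, is also in the alveolar list.

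Several transcription factors of the pharynx and kidney changed within lists that did not shift as sets. Of 11 thymic and parathyroid genes, the eyes absent gene Eya1 (1.41 ± 0.10) and Pax9 (1.27, adjusted p = 0.063 without control 3) rose and Tbx1 fell (-1.49 ± 0.09), and adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.708). Of 22 kidney genes, 4 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.656). Pax8, Sall1 (0.82 ± 0.10) and the endocytic receptor gene Lrp2 (0.76 ± 0.07) were higher and the receptor gene Ret lower (-0.85 ± 0.08). Of 18 genes of peripheral neurons and Schwann cell precursors, 1 rose and 2 fell, and 3 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.98). Besides Ret these were Erbb3 (-0.57) and Fabp7 (0.56), with adjusted p up to 0.145 without control 3 and 0.109 without control 1. Of 28 genes of the central nervous system 0 passed, also when adjusted over the list alone (camera adjusted p = 0.596), the smallest p belonging to Dcx (0.22, adjusted p = 0.138) and Nhlh2 (0.13, adjusted p = 0.387). Most members of these lists were dim as well. In controls, 3 of 11 thymic, 4 of 22 kidney, 4 of 18 peripheral nerve and 3 of 28 central genes read above the array median.

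In the list of anterior and middle genes of the Hox clusters, which pattern the body axis, 5 of 18 members were higher. None fell, and 13 did not pass. The list median was 0.16 (camera adjusted p = 0.000233, adjusted p = 0.15 with an estimated correlation), and 6 rose adjusted over the list alone. Hoxb6 rose from 6.97 ± 0.03 to 7.50 ± 0.15 (SD, n = 3), a difference of 0.53 ± 0.08 (SE, adjusted p = 0.00577). Hoxb2 (0.57), Hoxb4 (0.35) and Hoxb3 (0.33) passed over all arrays, with adjusted p up to 0.0708 without control 2, 0.119 without control 3 and 0.119 without control 1.

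**Figure D4:**
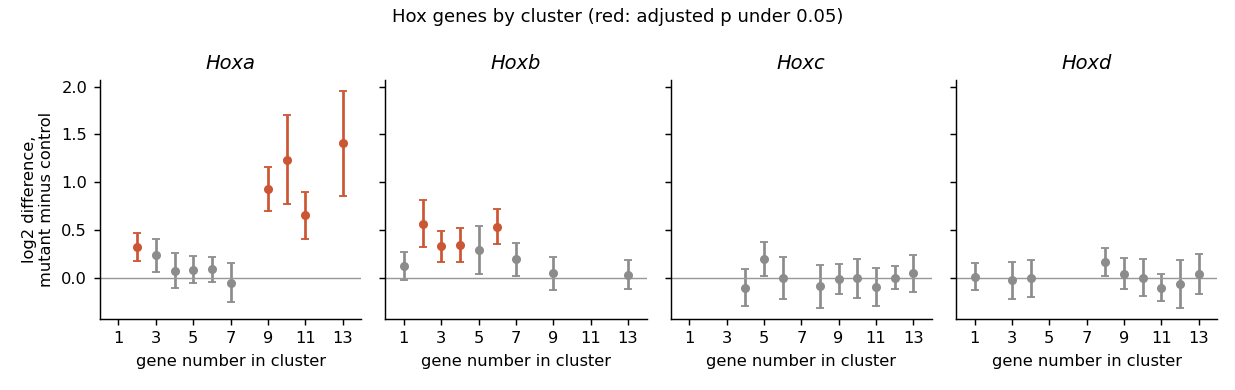
Log2 difference, mutant minus control, with 95% confidence intervals, of the measured Hox genes of the 4 clusters against their number in the cluster, with genes past an adjusted p of 0.05 in red. Hoxa9, Hoxa10, Hoxa11 and Hoxa13 lie between 0.66 and 1.41, and 0 of the posterior Hoxc and Hoxd genes pass.

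Among lists for cells that lung tissue contains or a dissection can carry over, camera with the preset correlation called the red cell list lower and the leukocyte list higher. Of 16 erythroid genes, 7 fell and 0 rose, with 9 that did not pass (median -0.27, camera adjusted p = 1.07e-05, adjusted p = 0.28 with an estimated correlation), and 8 fell adjusted over the list alone. The anion exchanger gene Slc4a1 (-1.09 ± 0.16), the haem synthesis enzyme Alas2 (-1.04 ± 0.16), Trim10 (-0.74 ± 0.10) and Epb42 (-0.43 ± 0.07) led them. Of 23 genes of macrophages and other leukocytes, 2 rose and 0 fell, with 21 that did not pass (median 0.19, camera adjusted p = 0.000978, adjusted p = 0.38 with an estimated correlation and 0.0944 by fry), and 4 rose adjusted over the list alone. The macrophage genes Csf1r (0.43) and Cx3cr1 (0.39) had adjusted p up to 0.0954 and 0.162 without control 2. Of 24 endothelial genes, Eng rose (0.37 ± 0.06, adjusted p = 0.0532 without control 2) and 0 fell, and adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.19). Of 24 heart muscle genes, Smpx fell (-0.99, adjusted p = 0.0793 without control 3) and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.844). The median of that list was 0.27 over all arrays and -0.17 without mutant 1 (camera adjusted p = 1.24e-06, 0.0905 with an estimated correlation and 0.00458 by fry). Of 22 skeletal muscle genes, Mylpf fell (-0.24, adjusted p = 0.162 without control 3), 0 rose, and 0 passed adjusted over the list alone (camera adjusted p = 0.998).

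Proliferation genes did not differ detectably. Of 29 cell cycle genes 0 passed, also when adjusted over the list alone (camera adjusted p = 0.68), and the smallest p belonged to Plk1 (-0.21, adjusted p = 0.0941) and Kif23 (-0.20, adjusted p = 0.105). Genes of the hypoxia response and glycolysis were higher in 4 of 19 members, with 0 falls and 15 that did not pass (median 0.21, camera adjusted p = 6.68e-05, adjusted p = 0.0726 with an estimated correlation), and 8 rose adjusted over the list alone. The mitophagy gene Bnip3 (0.76 ± 0.07, adjusted p = 0.000432) and the kinase gene Pdk1 (0.41 ± 0.07) rose, while the glycolytic genes Ldha (0.22) and Aldoa (0.21) had adjusted p up to 0.155 without control 3 and 0.171 without control 2. Of 18 p53 targets and apoptosis genes, 2 rose and 2 fell, and 4 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.596). The antiproliferative gene Btg2 fell (-0.95 ± 0.06) and Polk rose (0.64 ± 0.10), while Perp (-0.59) and Trp53inp1 (0.35) had adjusted p up to 0.167 without control 2 and 0.179 without control 3. Of 21 immediate early and heat shock genes, 4 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.0769), namely Btg2, Ccn1 (-0.68 ± 0.08), Jun (-0.58 ± 0.06) and Jund (-0.51, adjusted p = 0.0811 without control 1).

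Over the 37 lists, camera with the preset correlation called 11, of which 8 were lower and 3 higher in the mutants. With an estimated correlation only the alveolar list was called, and fry called 14. When the 6 arrays were split into other groups of 3, the preset correlation called up to 12 lists and the estimated correlation 0. The number of preset calls alone thus did not set the real split apart. Those other splits mix the genotypes unequally and keep part of their difference, so their calls need not be chance. The signs of median, mean and test differed for the goblet, Wnt, kidney, thymic, thyroid, liver, skeletal muscle and intestinal lists, none of which was called.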

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

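A signal appeared in features that the comparison by gene did not use, and it was looked at because control and mutant lungs differed there too. Among the 12146 features with no row in the platform annotation, 119 were higher and 48 lower in the mutants (1.37%). The threshold was a limma adjusted p under 0.05 over all features. Among the 1613 features with several gene symbols, 20 were higher and 8 lower (1.74%). With the same adjustment 828 of the 19946 genes changed, a larger share. Any genes these features belong to are unnamed here, and no explanation was tested.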

How the results depend on the processing

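None of the 1528 changed genes turned its direction in the alternatives for normalization, filter, features, moderation, weights, block, covariates or left-out arrays. Testing all features gave 828 changed genes, 393 higher and 435 lower, and 54.2% of the calls were kept. A fold of at least 1.5 left 549, with 241 higher and 308 lower, and an adjusted p under 0.1 gave 1165 higher genes (2239 in all). With each array left out the count ran from 774 to 1745, with 359 to 862 higher and 414 to 883 lower. It was 876, 793 and 774 without control 1, control 2 and control 3, and the cause was not tested. Quantile normalization kept the count (1532) but 43.5% of the changed genes were higher, against 50.1%, and the median shift over all genes stayed within 0.02 in every alternative. The Foxp1 difference ran from -0.37 to -0.22 with an array left out and passed only without mutant 3. Foxp2 and Foxp4 passed in every alternative.

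Same-numbered control and mutant arrays did not deviate together (r = -0.07, 0.05 and 0.15 across genes, and -0.12, 0.0017 and -0.07 without sex-linked genes), and only the arrays numbered 3, both male, correlated best with each other. The replicate numbers were therefore not taken as pairs. With a replicate block 1137 genes changed and 70% of the calls were kept. Sex as a covariate gave 1215 genes, and the heart list as a covariate, chosen after seeing the data, 1687.

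Of the 120 genes that the rule names and that passed the threshold, 79 passed in all alternatives run for them and 41 lost the call with at least 1 array left out. These were 33, 38 and 36 genes without control 1, 2 and 3, and 14, 8 and 19 without mutant 1, 2 and 3.

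Of the 11 lists called with the preset correlation, 1 was called with an estimated correlation, and the immune list was also lost by fry. Some lists that were not called passed in single alternatives, namely the ciliated and immediate early lists in 3, the hedgehog list in 2, and the endothelial and mesenchymal lists in 1. The test's direction turned in some alternatives for 11 lists, of which 0 were among the 11 called, so no direction is read from them. Of the 44 turned directions, 1 passed the threshold, that of the heart muscle list without mutant 1 with the preset correlation (median -0.17). Its adjusted p was 0.0905 with an estimated correlation and 0.00458 by fry. The heart muscle median ran from 0.48 to -0.17 over the left-out arrays and was -0.038 with the heart covariate. The cause of the other turns was not tested. The values given for them are list medians, which can keep their sign where the test's direction turned. Over the left-out arrays they ran from -0.040 to 0.025 for cell cycle, -0.022 to 0.076 for central neurons, -0.043 to 0.012 for intestine, -0.050 to 0.011 for liver, -0.104 to -0.029 for mesothelium, -0.065 to 0.072 for peripheral nerve, -0.086 to 0.020 for retinoic acid, -0.089 to 0.041 for skeletal muscle and -0.067 to -0.021 for thyroid. Quantile normalization turned peripheral nerve (-0.021), retinoic acid (-0.063) and skeletal muscle (-0.031). Median centring turned intestine (0.00012), and testing all features turned liver (-0.029). The trend and robust fit turned intestine (0.00025) and skeletal muscle (-0.015), and array weights turned intestine (0.010), peripheral nerve (0.042) and skeletal muscle (0.0026). The replicate block turned peripheral nerve (-0.0063) and skeletal muscle (-0.015), the heart covariate central neurons (-0.0033) and liver (-0.041), and fry retinoic acid (-0.044). Ranks turned intestine (0.00025), liver (-0.029), peripheral nerve (-0.0063) and thyroid (-0.035). Leaving out members of several lists turned hedgehog (0.022), liver (-0.053), mesothelium (-0.0058), peripheral nerve (0.0054), retinoic acid (-0.034) and thyroid (-0.045). The deposited values hold no detection calls. Genes silent in one sex give a rough level of background, which differs between features: Xist read 5.51 and 5.77 in the male lungs, and the Y-linked genes had means from 4.47 to 4.60 in the female lungs. Of the 12 largest falls, 5 had a mutant mean within this range, those of Tinag (4.83), Muc1 (5.64), Slc15a2 (5.29), Cfi (5.30) and Anxa1 (5.52). Sftpc (5.80) and Cldn18 (5.87) lay just above it, so the true folds of these 7 genes may be larger than those printed. Of the 12 largest rises, 0 had a control mean within it. Those of Frzb (5.81), Mab21l2 (5.86) and Car4 (5.92) lay just above, so their folds may be larger too.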

Other observations

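The genes and gene families in the first 2 paragraphs, and every test below except the counts over other splits of the arrays, were chosen after the values were seen. Bootstrap intervals below were drawn over the genes of a list and not over embryos. They treat genes as independent and do not measure the spread between embryos. Some gene families held more calls in one direction than genes elsewhere. Families were taken as genes sharing the letters before the first digit of their symbol, with at least 8 measured members, and 321 of them were tested in both directions with a one-sided Fisher's exact test, 642 tests in all. Of the 12 protocadherin genes with symbols in Pcdh, which encode cell adhesion molecules, 5 rose (adjusted p = 0.0166), against 3.81% of genes elsewhere, and Pcdh11x fell (-0.28, a call that ended with any one array left out, adjusted p up to 0.186 without control 3), while 0 of the 22 protocadherin genes with symbols in Pcdhb changed. The 5 were Pcdh7 (1.46 ± 0.08), Pcdh10 (1.34 ± 0.09), Pcdh20 (0.95 ± 0.09), Pcdh19 (0.42 ± 0.07) and Pcdh18 (0.26, adjusted p = 0.173 without control 2). In the lipid transporter family Abca, 5 of 16 genes rose (adjusted p = 0.0374) and 2 fell, Abca3 and Abca13 (adjusted p = 1). Those that rose were Abca5 (0.51), Abca6 (0.47), Abca8a (0.47), Abca8b (0.32) and Abca9 (0.63), which lie next to each other in the gene order of GRCm38.p6, and only Abca5 and Abca6 passed with each array left out. The adjusted p was up to 0.056 without mutant 3 for Abca8a, 0.162 without control 1 for Abca8b and 0.177 without control 3 for Abca9. Genes in one segment are not independent, so this p is too small. The Arid family of DNA-binding genes (4 of 10 higher, adjusted p = 0.0401) and genes whose symbols start with St, a mixed group that includes sialyltransferases (6 of 25 lower, adjusted p = 0.0374), also passed, but 5 of the same 25 St genes were higher (adjusted p = 0.184), so that group went both ways.

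Among Hox families, 5 of 10 Hoxa genes rose (adjusted p = 0.0113) and 4 of 9 Hoxb genes (adjusted p = 0.0374). Each of these families is 1 gene cluster, so these p values are too small as well. Hoxa13 (1.41 ± 0.24), Hoxa10 (1.24 ± 0.20), Hoxa9 (0.93 ± 0.10) and Hoxa11 (0.66 ± 0.11), which pattern caudal structures and limbs, read between 5.84 and 6.53 in controls, in the lower part of the array's range. Hoxa13 had an adjusted p of 0.0528 without control 3, and the other 3 passed with each array left out. Hoxa2 was at 0.33, with an adjusted p of 0.0923 without control 3.

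Whether other groupings of the arrays give as many calls was counted over the 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. Only the real split, 1 of 10, gave changed genes, with 1528 against at most 0 in any other split, and 765 against 0 for higher and 763 against 0 for lower genes. For lists with the preset correlation, 4 of the 10 splits called at least as many as the real 11, the highest other being 12. With an estimated correlation the real split called 1 list and the others 0. The other splits mix the genotypes unequally, so a real difference remains in part for the lists and adds to the spread for single genes. They are thus no measure of what chance alone would give.

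The fall of lung epithelial genes was set against a lower share of epithelial cells in the mutant lungs. A lower share would lower genes made only in epithelium by one fold. The 35 alveolar, tip and airway genes above the array median in controls had a median of -0.84 and the 23 genes shared by most epithelia -0.42, a difference of -0.42 with a 95% bootstrap interval from -0.79 to 0.077, which by itself decides nothing. Gene by gene, 17 of the 35 had a 95% interval below that of the shared genes' median (-0.57 to -0.29). This held for 15 to 18 with an array left out, and 7 lay above it, so these genes did not share one fold. Members of the shared list differed too, with Krt7 (-1.57 to -1.31) and Krt8 (-1.33 to -0.72) also below it. Genes made outside the epithelium as well would fall less, and which members those are was not known from a list. For the 17 lung genes that fell further than the shared genes' median, these values argue against a lower share as the whole cause. This holds as far as the shared genes are made only in epithelium. A lower share as part of the cause stays open. For the shared genes themselves a lower share stays open, as their upper quartile was -0.26, and it cannot be told apart from lower expression per cell without counts of cells. Lower expression per cell and a loss of particular epithelial cell types stay open for the lung genes, and neither was tested.

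The fall of smooth muscle genes, in a tissue the Cre does not reach, was set against heart tissue carried over with the controls, which would lower the heart genes in the mutants at least as far. Over all members the medians were 0.27 for heart and -0.40 for smooth muscle, but most heart genes are dim here and cannot fall far. Among members above the array median in controls, the 7 heart genes lay above the 17 smooth muscle genes by 0.73 (95% bootstrap interval from -0.65 to 2.25), and without mutant 1, whose heart list lay 1.10 above the controls, by -0.021 (-0.68 to 1.51), so heart tissue stays open. Smooth muscle of other organs carried over with the controls was not tested. The smooth muscle list had quartiles of -1.76 and -0.22, unequal folds that speak against a lower number of smooth muscle cells alone for genes made only there, but which members those are was not known from a list, so this stays open as well. A loss of an epithelial signal to the mesenchyme, such as Shh, may be part of it, but no test of that was made. Shh was at -0.96 and did not pass over all arrays (adjusted p = 0.101), while Hhip fell over all arrays (-2.32). Without mutant 2 Shh passed at -1.34 (adjusted p = 0.00104), as did the Shh target Ptch1 at -0.75 (adjusted p = 0.0138). Mutant 2 had the highest Shh value of the mutants, so the p values without it are no support for such a loss.

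The rise of posterior Hoxa genes was set against tissue of the caudal body carried over with the mutant lungs. Such tissue can bring the posterior Hoxc and Hoxd genes too. Their median was -0.0012 (95% bootstrap interval over genes from -0.07 to 0.05) and 0 of 10 changed. All 4 posterior Hoxa genes rose, with a median of 1.08. The difference was 1.08, with a bootstrap interval over genes from 0.66 to 1.41. Genes of 1 cluster are not independent, so these intervals are too narrow. The Hoxc and Hoxd genes read 5.33 to 6.23 in controls. Their median (5.71) lay at the level of genes silent in one sex (up to 5.77), where the array compresses differences. Hoxd11 (6.23) and Hoxd9 (6.16) read above that level and were at -0.10 and 0.05. Hoxa11 and Hoxa13 rose from 5.84 and 5.96, so a low level does not by itself prevent a rise. With the median at background the test does not decide, and carried-over tissue stays open. A strain-derived segment beside the floxed genes was the other explanation tested. Of the 150 genes measured nearest to Foxp1, Foxp2 and Foxp4, 14 changed (9.33%), against 7.64% of other genes, an odds ratio of 1.24 (0.66 to 2.17, Fisher's exact test, two-sided p = 0.439), and 0 of the 4 posterior Hoxa genes were among them. The interval is too wide to exclude such segments, genes in one segment are not independent, and a segment can reach beyond the 25 genes on either side that were counted. Hoxa lies on the same chromosome as Foxp1 and Foxp2, so strain differences near the floxed genes or elsewhere stay open beside a change in Hoxa regulation in the mutants, which was not tested.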
